A study of Mus musculus with 9 samples.

How the data were processed

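RNA from cultured mouse satellite cells, the muscle-resident stem cells, was measured by RNA sequencing in 9 samples. Per the labels, the cells came from limb skeletal muscle of pooled male and female newborn mice and were grown on collagen-coated dishes. Total RNA was made into TruSeq libraries, per the labels' protocols. The samples cover 3 media and 4 passages, written P0, P1, P2 and P15, with 1 sample for each combination that was grown. F10 medium was used at P0. Its serum and FGF are not given for that sample, so differences from it cannot be told apart from those of serum or FGF. T cell medium, a 50:50 mixture of F10 medium with 15% serum and T cell conditioned medium plus 2.5 ng/ml FGF, was used at all 4 passages. Cytokine medium was F10 medium with 15% serum to which IL-1α and IL-13 were added at 5 ng/ml each, IFN-γ and TNF-α at 10 ng/ml each, and FGF at 2.5 ng/ml. It was also used at all 4 passages.

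The deposited table gives RPKM values (reads per kilobase of gene model scaled to the number of reads), per the file headers, for 11148 rows, each with an Ensembl gene identifier and a gene name. TopHat2 2.0.1, HTSeq 0.5.4p2 and the genome build mm10 are named without roles, per the submitters' processing notes. The gene annotation, its build, the strand setting and the way the RPKM were scaled are not given in the sources used here. RPKM are already divided by depth and length, so no count test was applied, and differences are on the log2(RPKM + 1) scale, which understates the change of genes near 0.

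The file headers number 2 columns per sample without saying what the numbers stand for. The columns of each sample are called run 1 and run 2 here as a label only. Their low values are whole multiples of the value of 1 read, within 0.02 of a read unit, which gave the relative depth of each column. The run 2 depth was 0.917 to 0.927 of the run 1 depth in every sample. Between the columns of 1 sample the chi-square per row was 0.37 to 0.559, where independent sampling gives 1, and between different libraries it was 1.71 to 2.15. The 2 columns therefore differed by less than the sampling noise, and their mean was counted as 1 sample. How the columns were made is not given in the sources used here. With exon lengths from the reference annotation, the value of 1 read put run 1 at 13.0 M reads (P15, cytokine medium) to 18.2 M reads (P1, cytokine medium). For the P0 library in F10 medium, single rows put the depth at 12.0 M reads (25th percentile) to 14.8 M reads (75th percentile), so read numbers and counting intervals are approximate.

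The gene names were checked before use, because the mean of the Actb row was 0.00264 RPKM, that of Hprt was 0.00274 and that of the olfactory receptor row Olfr631 was 208. Identifiers were matched to GENCODE vM21 on the mm10 assembly (11105 of 11148 matched). For each chromosome, a stepwise offset between row coordinates and annotated exons was fitted to the values by maximum likelihood, on a grid of 40 bp up to 8 Mb, with a cost of 9 log-likelihood units per change of offset. The fit gave 98 segments. Of these, 87 with 10135 rows had offsets over 2000 bp. A name was used only in a segment that starts a chromosome and in which an offset of 0 was at most 5 log-likelihood units worse than the best offset. The last 3 rows of such a segment were left out where another followed. The mitochondrial rows were kept without an offset fit, and 6 of the 13 were below 1 RPKM in every library, so their names are in doubt. This rule for usable names was chosen after the data were seen. It kept 834 rows, 7.5% of the table. Of these, 473 lie on chromosome 16, 145 on chromosome 19, 77 on chromosome 8, 37 on chromosome 5, 28 on chromosome 18, 25 on chromosome 9, 24 on chromosome 3 and 12 on chromosome 17, and 13 are mitochondrial. On chromosome 16 the best offset was -240 bp, at which the median row covers 64.2% of its own exons, so levels there can be underestimates. An offset of 0 was 4.67 log-likelihood units worse there, just under the limit of 5. A slightly lower limit would have left out its 473 names. On simulated offsets, 99.3% of rows on chromosome 3, 99.1% on chromosome 9 and 84.9% on chromosome 19 were placed within 500 bp. Of 60 rows simulated without an offset on each, the rule kept 56 on chromosome 3, 57 on chromosome 9 and 0 on chromosome 19. No row was kept wrongly on chromosomes 3 and 9, and chromosome 19, where no row was kept, gives no test of that. The simulated values were drawn from the model used in the fit, with few changes of offset and offsets well under 8 Mb. The real fit often had more segments and larger offsets, and some kept segments were shorter, such as that with 12 rows on chromosome 17. The simulation is easier than these cases and does not test them. The other rows entered the fits, where they share the estimate of spread and the p-value adjustment, but apart from Actb, Hprt and Olfr631 above no value of theirs is reported under a gene name. No coordinates were converted between builds. Coordinates in the text are those of the GENCODE annotation.

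Rows with at least 1 RPKM in 1 or more of the 9 libraries were tested, 3686 in all, of which 597 had a usable name. The design has 1 library per medium and passage. Comparisons of single libraries therefore have no p-value, and genes at or beyond a 2-fold difference were counted. The 8 libraries in T cell or cytokine medium were fitted together with limma 3.58.1 in R 4.3.3 (eBayes with trend), with medium and passage as factors. The error of that fit is the medium-by-passage residual (3 degrees of freedom), moderated by eBayes toward that of the other rows (prior of 3.8 degrees of freedom). Its p-values ask whether a medium or passage difference is larger than this error. A gene's own variation between passages or media therefore counts only in part. Nothing in the labels says that passages are independent cultures, and passages of 1 medium can share a culture, so these p-values measure only the spread between these samples. Adjusted p-values are limma's with Benjamini-Hochberg adjustment over the 3686 rows, and calls were made at 0.05. A further limma fit on the 4 within-passage medium differences compared P15 with P0 to P2. It was chosen after seeing the data. P15 gives 1 difference, so the error of this fit holds no spread of P15. It comes from the spread of P0 to P2, moderated by limma toward that of the other tested rows. In simulated values for the fit across media with 200 changed rows among 3686, 99.0% of 2-fold and 99.8% of 4-fold changes were recovered, and 5% of calls were false. This simulation has equal medium effects at every passage.

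Per comparison, the text names up to 10 genes with the largest rise and 10 with the largest fall among those with at least 5 RPKM on the higher side. For the fits, these also had to pass the test, and where fewer than 10 passed, genes with the same sign are named as not passing. Predicted gene models were skipped. This rule, the gene lists and the tests of the comparisons, other than that of the medium difference at P15, were fixed before the data were examined. So were the alternatives not named below as chosen later. For the tests of explanations in the closing sections, the timing is given there. The restriction to usable names, the skipping of rows with several names and the minimum of 3 measured genes for a list test were chosen after they were seen. Of the 27 gene lists, 16 had at least 1 measured gene with a usable name and 2 had at least 3, the TNF and IL-1 (NF-κB) response list and the mitochondrially encoded list. These 2 were tested with limma's camera (preset correlation 0.01, alternatives with an estimated correlation and with fry) and, for single libraries, by the percentile of their median among 10000 random lists matched on mean expression. The genes planned to be named in every comparison, such as Pax7, Myod1 and Mki67, are not reported here because their row names could not be used. Other analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

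Alternatives were a pseudocount of 0.1 or 0.5, no filter, a filter of 5 RPKM, rescaling each library to the same sum, median-ratio scaling, quantile normalization, a 4-fold threshold, limma without trend or with robust estimation, a 2-fold minimum, each passage left out, and fits without the passage term or with late against early passages only. Chosen after seeing the data were same-sum rescaling and quantile normalization for the lists in single libraries, run 1 columns alone, a fit of rows with usable names alone, and genes with at least 50% of their own exons at the fitted offset.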

Results

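Gene expression was compared in mouse satellite cells cultured in conventional F10 medium, in T cell conditioned medium or in a medium with 4 cytokines, with the aim, per the series labels, of comparing expression profiles between these treatments. The 9 libraries were 1 from F10 medium at P0, 4 from T cell medium at P0, P1, P2 and P15, and 4 from cytokine medium at the same passages. Estimated depth was 14.8 M reads for P0 in F10 medium. In T cell medium it was 13.4, 16, 16.4 and 15.8 M reads at P0, P1, P2 and P15, and in cytokine medium 15.1, 18.2, 15.8 and 13.0 M reads. There was 1 library per medium and passage, so single-library differences have no replicate check, and intervals on them cover counting error only.

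Most row names in the table did not go with their values, and gene-level results are limited to 597 expressed genes whose names could be used. Rows of universally expressed families, such as ribosomal protein and proteasome genes, reached a mean of 1 RPKM in 24 of 25 cases (96.0%) where names were used and in 65 of 225 cases (28.9%) elsewhere. Of all rows, 66.5% reached 1 RPKM where names were used and 25.8% elsewhere. The names used were chosen by a fit to the same values, so these shares are partly set by that choice. Row names on the remaining segments, including those of most satellite cell, cell cycle and interferon response genes, carry no result here. Coordinates are those of GENCODE on mm10.

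**Figure D1:**
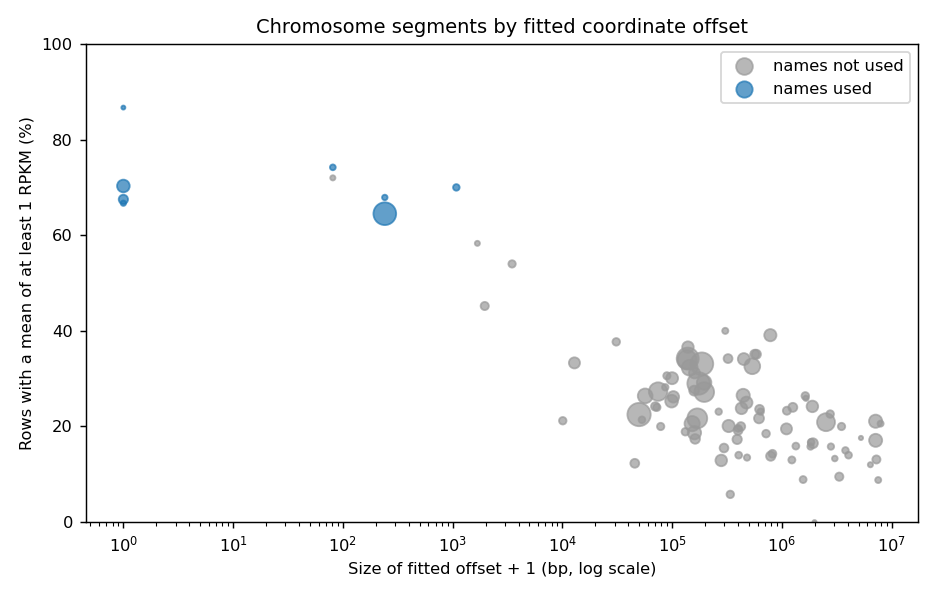
Each point is a chromosome segment, placed by the size of its fitted coordinate offset (bp plus 1, log scale) and by the percentage of its rows with a mean of at least 1 RPKM, with area growing with the number of rows. The 8 segments whose names were used (blue) lie at small offsets, with 64.5% to 86.7% of rows at 1 RPKM or more.

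T cell medium was compared with F10 medium at P0. The genes with the largest excess in T cell medium among those with at least 5 RPKM were Dtx3l and Parp9, which encode partner proteins of an interferon-induced ubiquitin ligase and ADP-ribosyltransferase pair, with log2 differences of 2.54 and 2.50. Dtx3l was at 0.346 RPKM in F10 medium and 6.81 in T cell medium, a fold of 19.7 (95% counting interval 13.6 to 28.5). Casp12, encoding a caspase associated with the endoplasmic reticulum, was higher by 2.36, Nfkbiz, a nuclear regulator of NF-κB target genes, by 2.16, and Rtp4, an interferon-inducible gene, by 1.63. Actn3, the α-actinin of fast fibres, was at 30.1 RPKM in F10 medium and 86.9 in T cell medium, a fold of 2.89 (95% counting interval 2.71 to 3.08). Myom2, a component of the sarcomeric M-band, was higher by 1.42 and Srl, which encodes the sarcoplasmic reticulum protein sarcalumenin, by 1.17, while the muscle glycogen phosphorylase gene Pygm differed by 0.11. Tvp23a was higher by 1.72 and Steap1 by 1.14.

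Among genes with at least 5 RPKM in 1 of the libraries, the largest deficits in T cell medium were those of Cd80, encoding a costimulatory ligand of T cells (-1.59), and of the basement membrane collagen chains Col4a1 (-1.42) and Col4a2 (-1.12). Col4a1 was at 36.8 RPKM in F10 medium and 13.1 in T cell medium. The myo-inositol transporter gene Slc5a3 differed by -1.27 and the adhesion gene Igsf11 by -1.11. Tiam2 (-0.92), Jam2 (-0.83), Gas6 (-0.76), Zfhx4 (-0.73) and Tbx1 (-0.68) differed by less than 2-fold. In all, 19 of the 597 genes were at least 2-fold higher and 7 at least 2-fold lower. They were 33 and 13 with each library rescaled to the same sum and 31 and 13 at a pseudocount of 0.1. The count of higher genes was 12 when only genes with at least 50% of their own exons at the fitted offset were counted.

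Cytokine medium was compared with F10 medium at P0. The largest excess was that of Parp14, an interferon-induced ADP-ribosyltransferase gene (chromosome 16, 35832874 to 35871544), with a log2 difference of 4.31. It was at 0.0912 RPKM in F10 medium and 20.6 in cytokine medium, a fold of 226 (95% counting interval 129.7 to 393). Parp9 (3.58), Dtx3l (3.39) and Batf2 (2.95), which encodes a transcription factor induced by interferon-γ, followed. Batf2 was at about 1 read in F10 medium, so its fold of 238 has a counting interval of 36.4 to 1560. Socs1, the feedback inhibitor of cytokine receptor signalling, was at 7.38 RPKM in F10 medium and 40.1 in cytokine medium, a fold of 5.44 (95% counting interval 4.82 to 6.13). Casp12 was higher by 2.63, Nfkbiz by 2.56, the stromelysin gene Mmp3 by 2.38, Tvp23a by 2.28 and Rtp4 by 1.97. The interferon-γ receptor chain Ifngr2 was higher by 1.57 and the interleukin receptor chain Il1rap by 0.85.

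Col4a1 and Col4a2 had the largest deficits (-2.57 and -2.26), followed by Pygm (-2.24) and Gas6, a ligand of receptor tyrosine kinases (-2.23). Of the Notch target list, Hes1 and Hey1 were measured, and both were lower, by -2.00 and -1.75. Hes1 was at 16.9 RPKM in F10 medium and 3.48 in cytokine medium, a fold of 0.206 (95% counting interval 0.167 to 0.254). Cd80 (-1.58), Igsf11 (-1.29), Srl (-1.16) and the protein kinase A inhibitor gene Pkia (-1.10) were also lower. Of the 597 genes, 26 were at least 2-fold higher and 16 at least 2-fold lower, with 31 lower at a pseudocount of 0.1 and 34 after rescaling to the same sum. The share of higher among these was 61.9%, and 50.7% when each library was rescaled to the same sum. That rescaling also makes the pseudocount smaller relative to RPKM.

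Of the TNF and IL-1 (NF-κB) response list, Steap4, Birc3, Mmp3, Mmp10 and Mmp13 were measured. At P0 all 5 were at least 2-fold higher in cytokine than in F10 medium and 2 were in T cell medium, with list medians of 1.54 and 0.81, both at the 100th percentile of random lists. Both medians were the value of Mmp13. Mmp3, Mmp10 and Mmp13 are neighbours on chromosome 9, and the random lists were matched on mean expression, not on position. In F10 medium they had about 8, 12 and 19 reads. The 7 mitochondrially encoded genes at 1 RPKM or more had medians of -0.19 in both media against F10 medium, at percentiles 0.7 for T cell and 0.9 for cytokine medium, and medians of 0 after quantile normalization. The mitochondrial COX2, COX3, ATP6, ATP8, ND3 and ND4L rows stayed below 1 RPKM in every library, although COX1 was at 2926 to 5077 RPKM. The names of all mitochondrial rows, including the 7 compared as a list, are therefore in doubt.

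The 2 comparisons with F10 medium share its library. At least 2-fold differences in both media were found for 13 genes upward and 6 downward. Unchanged libraries simulated around that shared control gave 0.84 and 0.7, and independent lists would give 0.827 and 0.188. Across genes, which are not independent replicates, the correlation of the 2 differences was 0.692 against 0.499 in the simulation, and 65.7% had the same sign against 66.6%. The covariance was 0.176 against 0.0323. With 1 control library no split was possible, and how much of the excess comes from the shared control is open.

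**Figure D2:**
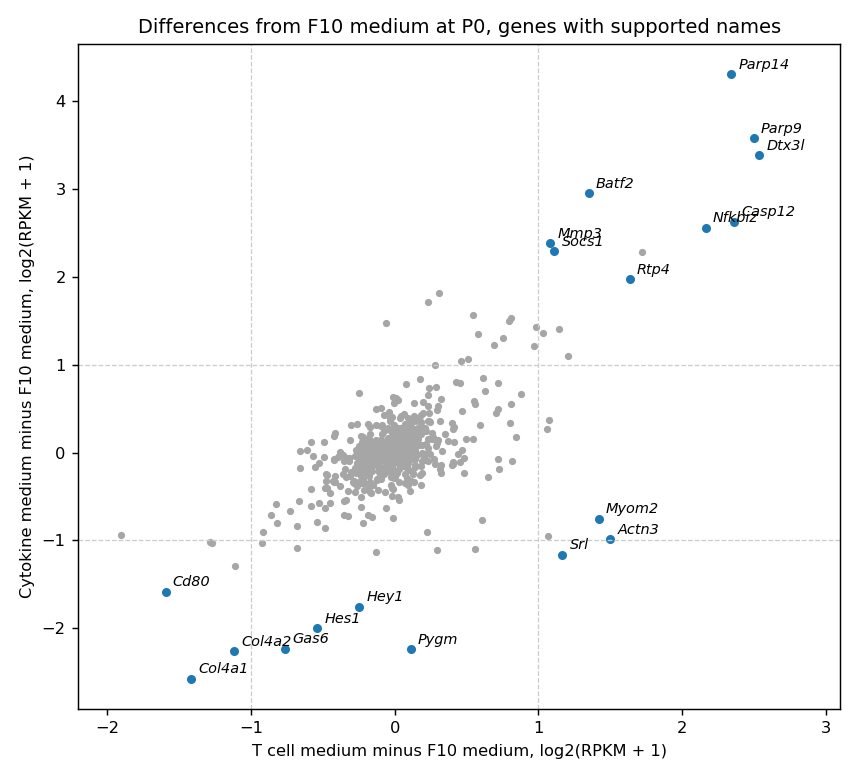
Each point is 1 of 597 genes, with its difference from F10 medium at P0 in T cell medium on the horizontal axis and in cytokine medium on the vertical axis, both as log2(RPKM + 1), and dashed lines at 2-fold. Parp14, Parp9 and Dtx3l lie at the upper right, Col4a1 and Col4a2 at the lower left, and Actn3, Myom2 and Srl to the right and below 0.

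The media were compared across passages. Relative to T cell medium, cytokine medium raised Batf2, Mmp3, Parp14, Col8a1, Socs1, Dtx3l, Parp9, Ifngr2, Cxadr and Litaf. Parp14 was at 24.4 ± 5.94 RPKM (SD, n = 4 passages) in cytokine medium and 6.20 ± 1.31 in T cell medium, a mean log2 difference of 1.81 ± 0.32 (limma adjusted p = 0.0018). Socs1 was at 42.1 ± 5.77 and 15.7 ± 1.72 RPKM, a difference of 1.36 ± 0.14 (limma adjusted p = 0.0017). Batf2 differed by 2.05 ± 0.64, Col8a1, a short-chain collagen, by 1.41 ± 0.61, Dtx3l by 1.07 ± 0.22, Parp9 by 1.04 ± 0.10, Ifngr2 by 1.01 ± 0.43, the adhesion receptor gene Cxadr by 0.91 ± 0.52 and Litaf by 0.78 ± 0.28. Mmp3 differed by 2.01 ± 1.37 with an adjusted p of 0.0447. All 10 were higher in cytokine medium at 4 of 4 passages.

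Actn3, Sema3d, Pygm, Srl, Hes1, Myom2, Gas6, Hey1, Col4a1 and Col4a2 were lower in cytokine than in T cell medium, at 4 of 4 passages each. Actn3 (chromosome 19, 4861216 to 4877909) was at 9.88 ± 4.26 RPKM in cytokine medium and 65.9 ± 45.5 in T cell medium, a mean log2 difference of -2.29 ± 1.37 (limma adjusted p = 0.0376). Pygm differed by -2.13 ± 1.02, Srl by -2.02 ± 1.26 and Myom2, the 1 measured member of the muscle differentiation list, by -1.9 ± 1.12. Hes1 was at 2.95 ± 1.51 and 13.2 ± 1.52 RPKM, a difference of -1.93 ± 0.71 (limma adjusted p = 0.0164), and Hey1 differed by -1.60 ± 0.80. Gas6 differed by -1.68 ± 0.81, Col4a1 by -1.39 ± 0.49 and Col4a2 by -1.34 ± 0.44. Sema3d, a secreted semaphorin gene, differed by -2.17 ± 1.25.

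**Figure D3:**
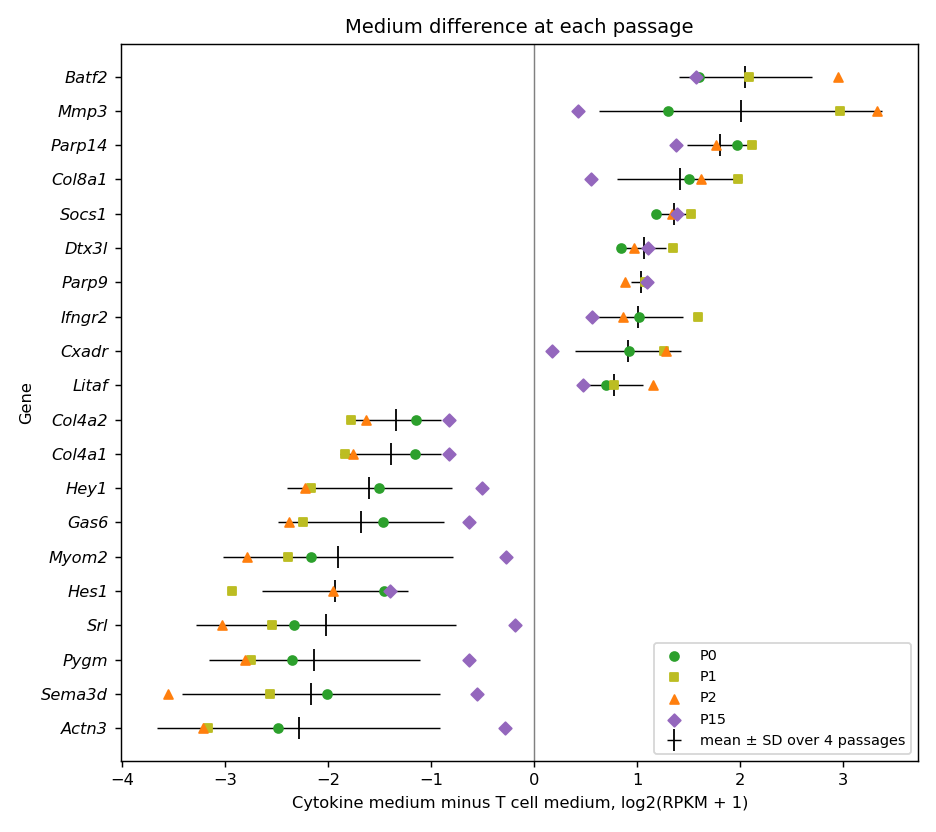
Cytokine minus T cell medium on the log2(RPKM + 1) scale for the 20 named genes, with 1 marker per passage and black bars for the mean ± SD over 4 passages. Parp9 and Socs1 vary least between passages. Actn3, Srl, Myom2, Pygm and Sema3d lie near 0 at P15 (-0.29, -0.18, -0.27, -0.63 and -0.55) and below -2 at P0, P1 and P2.

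Of the 597 genes, 43 rose and 39 fell at an adjusted p under 0.05, and among all 3686 rows 175 rose and 176 fell. The count depended on the passages used. Without P0, 5 genes rose and 0 fell, without P1, 4 and 1, without P2, 6 and 0, and without P15, 60 and 56. Where 0 fell, limma gave 74 (without P0) and 80 (without P2) downward at an unadjusted p under 0.05. Without a passage term 16 rose and 6 fell. With no filter on low values 0 passed in limma, where 119 genes had an unadjusted p under 0.05 upward and 111 downward.

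Of the NF-κB response list, 2 of 5 genes, Mmp3 and Birc3 (1.18, limma adjusted p = 0.0296), rose with adjustment over all rows. When adjusted over the list alone, 4 rose and 1 fell. Mmp10 differed by 2.82 and Mmp13 by 2.28, with adjusted p of 0.0618 and 0.107 over all rows, and Steap4 by -0.40. The list as a whole did not pass camera (adjusted p = 0.122), with an adjusted p = 0.59 with an estimated correlation. The fry test of limma, adjusted over the lists tested, gave an adjusted p = 0.168 for 1 direction and an adjusted p = 0.06 for either direction. The mitochondrially encoded list had a median of -0.17, with 0 of 7 genes passing over all rows or over the list alone and a camera adjusted p = 0.145 (limma; COX1 alone had an unadjusted p under 0.05, 0.0393).

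The list differences between the media varied by passage. The NF-κB response list had medians of 1.30, 2.97 and 3.33 at P0, P1 and P2 (percentile 100 each) and of 0.36 at P15 (percentile 99.1), where 0 members were at least 2-fold higher. Against P0, its medians at P1, P2 and P15 were 0.41, 0.60 and -0.63 in cytokine medium (percentiles 99.8, 99.9 and 0.1). In T cell medium they were -0.35, -0.27 and -0.04 (percentiles 4, 1.8 and 59.2), the last being 0.05 after quantile normalization. The members did not move together at P15. In cytokine medium 1 was at least 2-fold higher than at P0 and 2 at least 2-fold lower. In T cell medium these were 2 and 1. Mmp10 rose by 1.82 in cytokine medium and 2.98 in T cell medium, while Mmp3 fell by 2.25 and 1.37. The mitochondrially encoded list had medians of -0.06, 0.15, -0.54 and -0.18 between the media at P0, P1, P2 and P15 (percentiles 7.4, 81.2, 0.3 and 1.9). Against P0, its medians at P1, P2 and P15 were 0.38, 0.21 and 0.36 in T cell medium (percentiles 99.7, 99.5 and 98.3) and 0.56, -0.19 and 0.19 in cytokine medium (percentiles 100, 0.7 and 84.1). Quantile normalization set these mitochondrial medians to 0, except that between the media at P2 (-0.20).

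Other lists had 1 or 2 measured members. Ciita, the regulator of class II antigen presentation genes, rose by 0.49 (limma adjusted p = 0.0412) and the stress response gene Sdf2l1 by 0.54 (limma adjusted p = 0.044). In the interferon-γ response list both measured genes, Parp14 and Socs1, rose, and in the Notch target list both, Hes1 and Hey1, fell. The S phase genes Cdc45 and Mcm4 differed by 0.41 and 0.33, at adjusted p of 0.0608 and 0.0683 in limma. For the FGF and ERK feedback genes, Fosl1 differed by 0.66 and Etv5 by -0.24 without passing. Fabp4 of the adipocyte list (0.45), Stmn2 of the nerve list (-0.13), Cyp51 of the cholesterol list (-0.14), Bcl6 of the IL-13 list (0.05), whose other measured member Socs1 rose, Il1rap of the receptor list (0.64), whose other measured member Ifngr2 rose, and Tfrc of the housekeeping list (0.09) did not pass either.

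At single passages, the number of genes at least 2-fold apart between cytokine and T cell medium was 23 at P0 (9 higher, 14 lower), 37 at P1 (20 and 17), 51 at P2 (22 and 29) and 8 at P15 (7 and 1). At P15, the share of higher genes among these was 87.5%, and 71.4% when libraries were rescaled to the same sum. The pseudocount is then also smaller relative to RPKM. At P2 the matrix metalloprotease genes Mmp10 (5.48), Mmp13 (5.27) and Mmp3 (3.33) and the neuropeptide gene Gal (3.35) had the largest excess, and Sema3d (-3.55), Actn3 (-3.21) and Srl (-3.03) the largest deficit. Gal differed by -0.15, -0.01 and 0.30 at P0, P1 and P15. In T cell medium Gal was at 14.6, 28.6, 3.39 and 17.9 RPKM from P0 to P15, and in cytokine medium at 43.8 RPKM at P2. With 1 library per medium, the larger count at P2 cannot be told apart from an unusual P2 library. At P15 the excess was largest for Batf2 (1.57), Socs1 (1.39), Parp14 (1.38), Stmn2 (1.13), Dtx3l (1.11), Parp9 (1.10) and Rtp4 (1.06), and Hes1 (-1.40) was lower. Between the media, the SD of the difference over the 597 genes was 0.427 at P0, 0.577 at P1, 0.729 at P2 and 0.26 at P15.

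The change of the medium difference at P15 was tested. It was smaller at P15 than at P0 to P2 for Actn3, Srl, Myom2 and Pygm. For Actn3 the log2 difference went from -2.95 at the early passages to -0.29, a change of 2.67 with a standard error of 0.31. P15 enters this test as 1 difference without a replicate, so the error holds no spread of P15. It comes from the spread of P0, P1 and P2, moderated by limma toward that of the other tested rows. The changes were 2.45 ± 0.28 for Srl, 2.18 ± 0.25 for Myom2 and 2.01 ± 0.22 for Pygm (SE, each with a limma adjusted p = 0.0489). Sema3d (2.16) and Hey1 (1.46), and in the other direction Mmp3 (-2.10) and Mmp10 (-3.26), also had differences nearer to 0 at P15, without passing. No gene of the 597 passed in the other direction, where 21 had an unadjusted p under 0.05. Without any difference, a share of 0.05 of genes would reach that over both directions. In T cell medium Actn3 was at 86.9, 50.8, 115.5 and 10.5 RPKM from P0 to P15, and in cytokine medium at 14.7, 4.79, 11.6 and 8.44. From P0 to P2 to P15, log2 values changed by -2.82, -2.82 and -2.11 in T cell medium for Actn3, Srl and Myom2. In cytokine medium they changed by -0.15, -0.37 and 0.07. Pygm differed from these, with -0.87 in T cell medium and a rise of 1.14 in cytokine medium. All 4 calls ended when P1 was left out (adjusted p = 0.216), after quantile normalization (adjusted p = 0.0811), in limma without trend (adjusted p = 0.0632), with no filter (adjusted p = 0.344 to 0.399) and with usable names alone (adjusted p = 0.0509 to 0.0524). The call of Myom2 also ended at a pseudocount of 0.1 (adjusted p = 0.0515) and with a filter of 5 RPKM (adjusted p = 0.109). Over the alternatives run and the 4 genes, the adjusted p ran from 0.0012 to 0.399 and the change from 1.92 to 2.91.

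**Figure D4:**
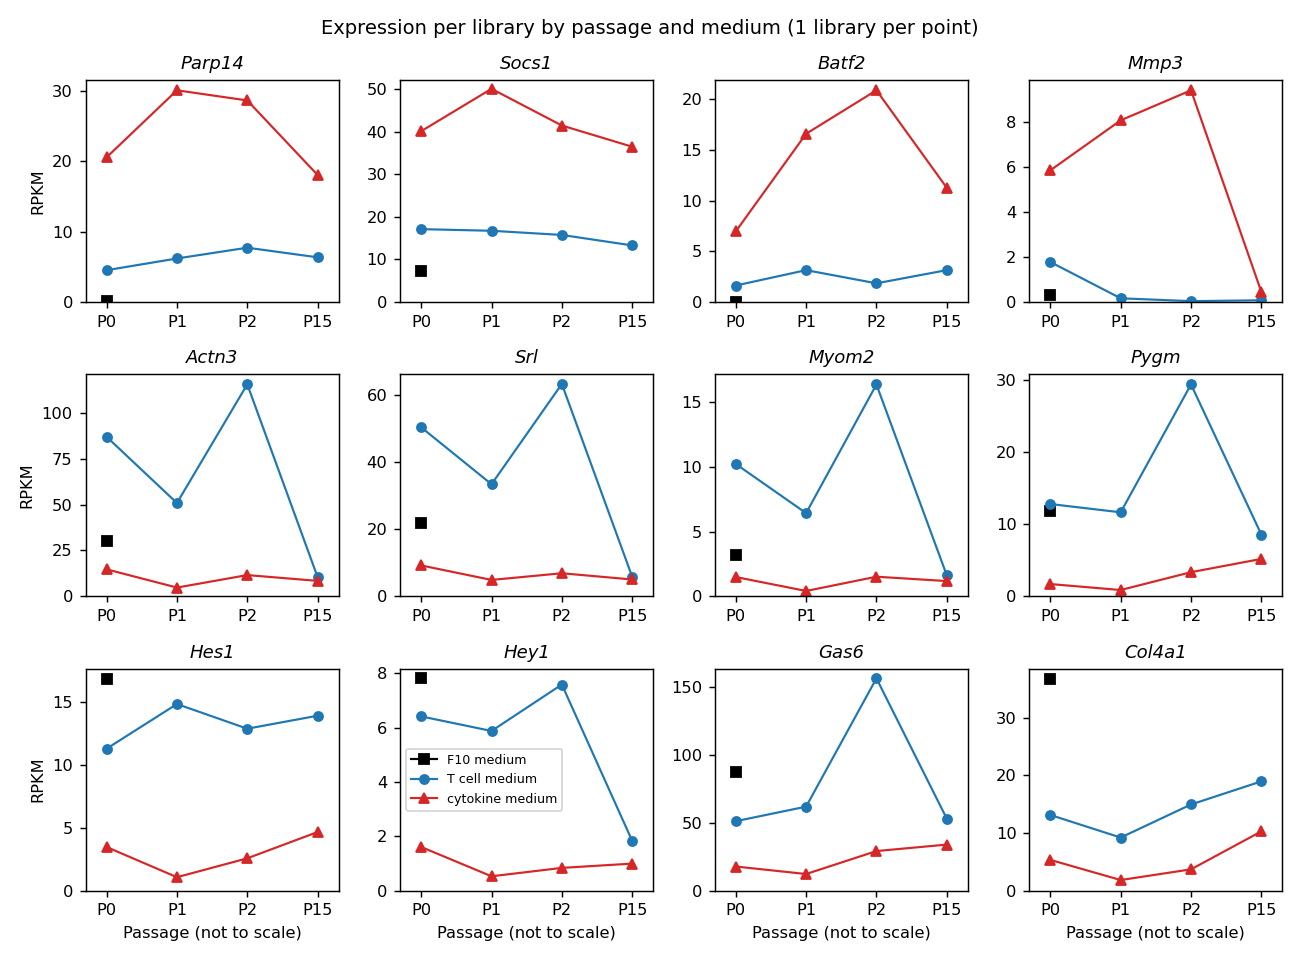
RPKM per library for 12 genes by passage, with 1 point per library and lines joining libraries of the same medium. Actn3, Srl and Myom2 in T cell medium are lower at P15 (10.5, 5.85 and 1.62 RPKM) than at P0, P1 and P2, while Parp14 and Socs1 stay higher in cytokine medium at each passage.

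P15 was compared with the earlier passages across media. Pdgfd, a platelet-derived growth factor gene, rose by 1.22 ± 0.20 (SE; limma adjusted p = 0.0402), the phospholipase gene Pla1a by 1.14 ± 0.14, Col4a2 by 1.1 ± 0.18, Cnih2 by 1.1 ± 0.17 and Nfkbiz by 0.65 ± 0.11. Adamts1, an extracellular metalloprotease gene, fell by 0.89 (limma adjusted p = 0.0104), Emp2 by 0.83, Unc93b1, which traffics Toll-like receptors, by 0.71 and Marf1 by 0.57. Stmn2, a neuronal microtubule regulator, had the largest difference, 2.33, without passing (adjusted p = 0.0805). In T cell medium Stmn2 was at 0.777, 8.01, 14.9 and 16.8 RPKM at P0, P1, P2 and P15. In cytokine medium it was at 0.799, 0.963, 22.3 and 38.0 RPKM. Much of its rise had therefore come by P2. Cxadr (1.00), Col4a1 (0.98), Gap43 (0.76), Fosl1 (0.73), Srl (-1.60), Actn3 (-1.48), Bbx (-0.70), Cdk6 (-0.63), Golgb1 (-0.53) and Kif5b (-0.52) did not pass either. The NF-κB response list had a median of -0.43 (camera adjusted p = 0.244) and the mitochondrially encoded list one of 0.11 (camera adjusted p = 0.244), with 0 members passing over all rows or over the list alone in limma. At an unadjusted p under 0.05 there were 2 members in each list, Steap4 and Mmp3 downward and COX1 and CYTB.

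Of the 597 genes, 8 passed upward and 6 downward, and the count varied with the passages used. It was 31 upward and 21 downward without P2, 0 and 2 without P0 (48 upward in limma at an unadjusted p under 0.05), 2 and 2 without P1, and 1 and 1 when the fit held only rows with usable names. Rescaling each library to the same sum gave 10 upward and 32 downward, and median-ratio scaling 14 upward and 6 downward.

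Passage steps within each medium were described against P0. In T cell medium, 7 genes were at least 2-fold apart at P1, 16 at P2 and 27 at P15. At P15 the largest differences were those of Stmn2 (3.33), Mmp10 (2.98), Pdgfd (2.45) and Cnih2 (2.01) upward and of Actn3 (-2.93), Srl (-2.91), Myom2 (-2.09) and Hey1 (-1.39) downward. In cytokine medium the counts were 8, 12 and 14. Stmn2 (4.44), Pdgfd (2.20) and Mmp10 (1.82) were higher at P15, and Mmp3 (-2.25) and Emp2 (-1.25) were lower. At P2 in cytokine medium Mmp13 (4.08), Stmn2 (3.69) and Mmp10 (3.68) led. Across the 597 genes, the P15 minus P0 differences in the 2 media, which share no library, had a correlation of 0.731, with 77.7% of the same sign. The 2-fold lists shared 6 genes upward and 2 downward, and 0 genes were on opposite sides.

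The median difference of all rows from P0 was -0.04 at P1 and -0.03 at P15 in T cell medium, and -0.20 and -0.21 with each library rescaled to the same sum. In cytokine medium it was -0.04 and -0.06, and -0.25 and -0.21 with the rescaling. With it, the share of higher genes went from 55.6% to 32.7% for P15 against P0 in T cell medium and from 71.4% to 47.4% in cytokine medium. At P1 it went from 42.9% to 29.0% and from 50.0% to 26.1%. Median-ratio scaling gave 88.9% at P1 in T cell medium and 100% at P2 in cytokine medium, where the main share was 75%. Same-sum rescaling also makes the pseudocount smaller relative to RPKM, so shifts with it are not those of scaling alone. Summed over the passage steps, it gave 206 genes at least 2-fold apart. A pseudocount of 0.1 gave 188, median-ratio scaling 86 and the main setting 84.

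Some named genes carry further limits. At the fitted offset the rows of Steap1, Pla1a, Mmp3, Sema3d and Parp9 cover 9.5%, 14.0%, 28.5%, 36.6% and 47.7% of their own exons, so their levels are uncertain. The rule for usable names kept 0 of 60 rows in a simulation of chromosome 19, so names there, such as Actn3, Pygm, Batf2, Gal and Cnih2, are less certain. Names on chromosome 16, such as Parp14, Parp9, Dtx3l, Socs1, Srl and Hes1, passed the limit of 5 log-likelihood units narrowly, at 4.67. Exons of Dtx3l and Parp9, of Cxadr and Btg3, of Tvp23a and Nubp1, of Fosl1 and Ccdc85b, of Cdc45 and Ufd1 and of Slc5a3 and Mrps6 overlap. The strand setting is not given and Slc5a3 and Mrps6 lie on the same strand, so reads in the overlaps cannot be assigned to 1 gene of a pair.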

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

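The test of a changed medium difference at P15 and each test below were chosen after the results were seen. Actn3, Srl, Myom2 and Pygm had a medium difference (cytokine minus T cell medium) that was less negative at P15 than at P0 to P2, by 2.67, 2.45, 2.18 and 2.01 on the log2 scale, by a test of the difference itself (limma, adjusted p = 0.0489 for each). P15 gives 1 difference, so the error of this test holds no spread of P15. It comes from P0 to P2, moderated by limma toward the spread of the other tested rows. All 4 calls ended without P1 (adjusted p = 0.216), after quantile normalization (0.0811), without trend (0.0632), with no filter (0.344 to 0.399) and with usable names alone (0.0509 to 0.0524), and over the alternatives run the adjusted p went from 0.0012 to 0.399.

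Exchanged labels of the P15 libraries would reverse the medium differences, and 0 of 14 other genes at least 2-fold apart at each of P0, P1 and P2 had a reversed difference at P15, which argues against an exchange. P15 libraries mixed with each other would leave every gene a like share of its RPKM difference, and the 4 genes kept 1.9% to 21.2%. Of the 14 other genes, 7 were above 21.2% even of their own largest early difference, with 77.1% for Col4a1 and 69.5% for Socs1, which argues against mixing as the whole cause but not against some mixing beside other changes. Scaling and a floor set by the pseudocount are argued against as the whole cause, since the smallest change over the 4 genes was 2.02 under 3 other scalings and 2.46 at a pseudocount of 0.1, although adjusted p passed 0.05 after quantile normalization, where changes were no smaller and most standard errors larger.

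The shrinkage is not particular to these genes, since others such as Mmp3 (5.2%) and Sema3d (9.9%) kept as little of their early RPKM difference. No biological explanation was tested, and a difference of medium or passage stays open. With 1 library per medium and passage, an unusual P15 culture, or a P15 library from another source, stays open as well.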

How the results depend on the processing

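Alternatives chosen after seeing the data are same-sum rescaling and quantile normalization for the lists in single libraries, run 1 columns alone, a fit of rows with usable names alone, genes with at least 50% of their own exons at the fitted offset, and the test of the medium difference at P15. In the order higher and lower for T cell against F10 medium (19 and 7), higher and lower for cytokine against F10 medium (26 and 16), and totals over the 4 passages between media (119) and over the 6 passage steps (84), a pseudocount of 0.1 gave 31, 13, 33, 31, 200 and 188, rescaling to the same sum 33, 13, 35, 34, 210 and 206, and a 4-fold threshold 5, 0, 9, 4, 33 and 19. A pseudocount of 0.5 gave 25 lower genes for cytokine against F10 medium, and genes with 50% of their own exons gave 12 higher for T cell medium. The same-sum rescaling also makes the pseudocount smaller relative to RPKM. For cytokine against T cell medium across passages (43 and 39), no filter gave 0 and 0, a 2-fold minimum 9 and 12, and no passage term 16 and 6. For P15 against the earlier passages (8 and 6), a pseudocount of 0.1 gave 10 lower, no filter 0 and 0, a filter of 5 RPKM 4 higher, same-sum rescaling 32 lower, median-ratio scaling 14 higher, quantile normalization 5 higher, a 2-fold minimum 4 and 0, genes with 50% of their own exons 5 higher, rows with usable names alone 1 and 1, and late against early passages alone 1 and 2. Leaving out each passage in turn gave 4 to 60 higher and 0 to 56 lower genes for the media, and 0 to 31 higher and 2 to 21 lower genes for P15. It gave 0 to 10 genes for the medium difference at P15 (4), which had 0 with no filter, after quantile normalization, without trend and with usable names alone. In these settings with 0 calls, limma gave at least 36 genes at an unadjusted p under 0.05. A share of 0.05 of genes would reach that without any difference. Dropping a passage leaves 2 residual degrees of freedom in the fits of 8 libraries and 1 in the fit of the differences. Counts rose as well as fell, with 60 higher and 56 lower genes for the media without P15, and the cause of the shifts was not tested. ND1 at P1 against P0 in cytokine medium (0.88) was 0 after quantile normalization, which gives the highest rows of each library equal values. The libraries of both media are paired by passage in the fits, and no passage term gives the unpaired counts above. Depth limits genes near 0, such as Batf2 in F10 medium at about 1 read.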

Other observations

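The test of rows in scrambled order within a chromosome was written before its result was seen, and the other tests here were chosen or written after results were seen.

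Of the 175 rows that were higher and 176 that were lower in cytokine than in T cell medium, 43 and 39 had a usable name. At P0 to P2, 15 rows were at least 2-fold higher and 38 at least 2-fold lower in cytokine medium at each of the 3 passages, of which 7 and 11 had a usable name.

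Row names that do not go with their values were weighed against 3 explanations. Gene models placed with coordinates of another build are consistent with universally expressed families reaching 1 RPKM in 96.0% of rows with a usable name. Cells with low expression of those families would give a low share everywhere, but the 28.9% was that of rows without a usable name. The rows with usable names were chosen by a fit to the same values, so this contrast is partly set by that choice. Of all rows, 66.5% with a usable name and 25.8% without reached 1 RPKM. Rows in scrambled order within a chromosome would fit an offset no better than shuffled rows, but the real rows of chromosomes 2 and 11 were better by a log-likelihood of 191.4 and 201.8 than the best of 5 shuffles. On chromosome 16 the gain was 7.0, which decides nothing, because at an offset near 0 each row lies on its own exons in any order. Among the nuclear rows with usable names, the median of universally expressed families was 28.8 RPKM against 4.23 for all. This gave a permutation p = 1e-05 over 100000 shuffles, the smallest they can give, which argues against a complete scramble of these rows. The shuffles pooled the chromosomes, so they do not test any single segment or a scramble of some rows only.

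Between cytokine and T cell medium, 351 rows passed in the real split of the 8 libraries. Of the 8 splits that part the libraries of each passage, 1 gave as many, the real one, and the highest other gave 0 rows, but 8 splits are too few for a share under 0.05.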
